A study of Mus musculus with 12 samples.

How the data were processed

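RNA came from breast tumours of 12 mice, 6 per genotype, with polyadenylated RNA sequenced as paired 100 bp reads on an Illumina NovaSeq, per the labels. The authors deposited raw read counts per Ensembl gene for each tumour, as whole numbers, and the total differs between tumours. The submitters' processing notes name fastp 0.23.1, STAR 2.7.9a, DESeq2 and the build GRCm38. The counting tool, annotation release and strand setting are not given in the sources used here, so reads in overlapping genes and in antisense partners could not be told apart. The authors' deposited comparison holds a log2 fold change, its standard error, a Wald score, a mean signal of normalised counts, and unadjusted and adjusted p-values per gene, per the file headers. Its direction was settled by correlation with the counts. Only the fold changes and adjusted p-values were used.

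The count table holds 55487 genes and no unnamed entry. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 18019, normalised with TMM, and tested with the quasi-likelihood F test (robust dispersion) for genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of F. A positive log2 fold change is higher in Bad3SA. CPM values are TMM-normalised, and means are given with the SD over 6 tumours. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, BLAST+ 2.17.0 and matplotlib 3.10.9 were used. Positions come from GENCODE release 21 for mouse on GRCm38, in which 260 of the gene identifiers have no entry.

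Before the data were examined, 41 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes Bad, then the 10 highest and 10 lowest fold changes among genes that passed with a mean log2 CPM of at least 1, leaving out predicted models, pseudogene names and receptor segments. This goes by name, so Rps3a3, whose name does not mark it as the pseudogene it is annotated to be, was kept. It adds the 4 members with the smallest p in each list that passed, up to 3 passing members of other lists, and 5 BCL2 family members. A gene that this rule names in the cholesterol synthesis list is not reported here. Lists with at least 5 tested members were compared with other genes by camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Ages were compared by exact permutation. Called genes within 5 Mb of Bad were compared with the rest by Fisher's exact test.

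Alternatives were DESeq2 size factors, the DESeq2 Wald test, limma voom with quality weights, no filter or at least 1 CPM in 6 tumours, a non-robust dispersion, end-point age as a covariate, the title number as a block, and each tumour left out. The fit was tested on simulated counts with 6 tumours per group over 17764 genes. It called 36.4% of genes with a true log2 change of 1 and 72.4% of those with a change of 2, with 6 unchanged genes called, so many changes of 2-fold would be missed at this number of tumours. Depth ran from 58096172 to 83296370 counts per tumour. Whether depth, the spread between mice or the number of tumours limited the calls most was not compared.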

Results

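RNA was measured in breast tumours of 12 MMTV-PyMT mice, in which the mouse mammary tumour virus promoter drives the polyoma middle T oncogene in mammary epithelium. Tumours came from 6 mice with wild-type Bad (Bad_WT) and from 6 mice carrying Bad3SA, a form of BAD that cannot be phosphorylated at its regulatory serines. BAD is a pro-apoptotic member of the BCL2 family, and the design asks how tumour transcripts differ when its phosphorylation is blocked. Each library was a separate mouse. Total counts ran from 58096172 (Bad3SA 5) to 83296370 (Bad_WT 2), and 3 counts corresponded to between 0.036 and 0.0516 CPM, the count scaled to library size. Spearman correlations between tumours, taken across genes, ran from 0.937 to 0.989. The first principal component held 29.0% of the variance and the second 19.9%. Bad_WT 6 lay at the low end of the first, and Bad3SA 4, 5 and 6 lay apart from the other tumours on the second.

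The Bad transcript did not differ detectably between genotypes. Bad (ENSMUSG00000024959, GRCm38 chromosome 19, 6941861 to 6951899) was at 47.0 ± 8.30 CPM in Bad_WT and 48.8 ± 12.4 CPM in Bad3SA (SD, n = 6 each), a log2 fold change of 0.05 (SE 0.17, edgeR adjusted p = 0.889). Bad overlaps Gpr137 on the other strand, and the strand setting of the counting is not given in the sources used here. A codon change leaves the transcript in place, so its level does not check the genotype labels. In the BCL2 family list, none of the 19 members tested passed, over all genes or adjusted over the list alone. The smallest p values belonged to Bcl2, which encodes the anti-apoptotic founder of the family (log2 fold change -0.47, SE 0.14, edgeR adjusted p = 0.139), and to Bcl2l11, which encodes BIM (-0.68, SE 0.22, adjusted p = 0.168). Bok, Pmaip1 and Bcl2l13 followed at -0.59, -0.73 and -0.28. The list of apoptosis execution genes had a median log2 fold change of 0.04 over 25 genes, and none of them passed.

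Of 18019 genes tested, 249 differed between the genotypes at an adjusted p under 0.05 (edgeR quasi-likelihood), 112 higher and 137 lower in Bad3SA. The change was at least 2-fold for 183 of them. Protein-coding genes made up 184 of the calls, with 60 higher and 124 lower, and pseudogenes made up 33, with 32 higher and 1 lower. DESeq2 called 998 genes, limma voom with quality weights 579, and the model with end-point age 73.

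Several genes were nearly silent in Bad_WT and abundant in Bad3SA. BC018473, annotated as an antisense RNA on chromosome 11 at 116752167 to 116759373, overlaps no other gene in GENCODE release 21. The annotation and strand setting of the counting are not given. It had 5 counts over the 6 Bad_WT tumours together and 395829 over the 6 Bad3SA tumours, or 968 ± 558 CPM in Bad3SA. St6galnac1, a sialyltransferase gene on chromosome 11 at 116765025 to 116775507, was at 0.161 ± 0.0965 CPM in Bad_WT and 89.9 ± 55.2 CPM in Bad3SA, and shares 98.0% identity with Gm11735. Ifi44l, an interferon-induced gene, had 21 counts in Bad_WT and 9672 in Bad3SA. Hmga1b and Rps3a3 also rose, by log2 5.47 (SE 0.37) and 6.29 (SE 1.24). Rps3a3 is annotated as a processed pseudogene lying within Pde4d on the same strand, and was at 0.756 ± 0.0856 CPM in Bad_WT and 59.1 ± 97.7 CPM in Bad3SA, with 250 CPM in Bad3SA 5 and 0.936 CPM in Bad3SA 3. Hmga1b is 99.8% identical to Hmga1 and Rps3a3 is 98.9% identical to Rps3a1, so reads could be divided between the copies. Nanos3, Slc47a1, Dcstamp, H2-Q7 and Oas2 rose by log2 3.82, 3.48, 3.37, 2.66 and 2.31.

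Robo1, Robo2, Fmn2 and Grik3 were among the genes that fell most. Robo1, which encodes a receptor for SLIT ligands, went from 27.8 ± 11.9 CPM in Bad_WT to 4.75 ± 2.65 CPM in Bad3SA (log2 fold change -2.54, SE 0.43, edgeR adjusted p = 0.00889). Robo2, its paralogue, changed by log2 -4.06 (SE 0.67), from 4.21 ± 5.10 CPM in Bad_WT, where Bad_WT 3 reached 14.4 CPM, to 0.251 ± 0.0681 CPM in Bad3SA. The formin gene Fmn2 changed by -5.11 (SE 0.75) and the glutamate receptor gene Grik3 by -2.88 (SE 0.63). Dcaf12l1, Them5, Nexmif, Atp6v0e2, Lrmda and Snhg18 lay between -5.03 and -2.26. Bad_WT levels of Grik3 (15.0 ± 16.3 CPM) and Dcaf12l1 (4.92 ± 5.46 CPM) varied as widely as their means, with 41.7 CPM of Grik3 in Bad_WT 6 and 14.1 CPM of Dcaf12l1 in Bad_WT 3. 

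**Figure D1:**
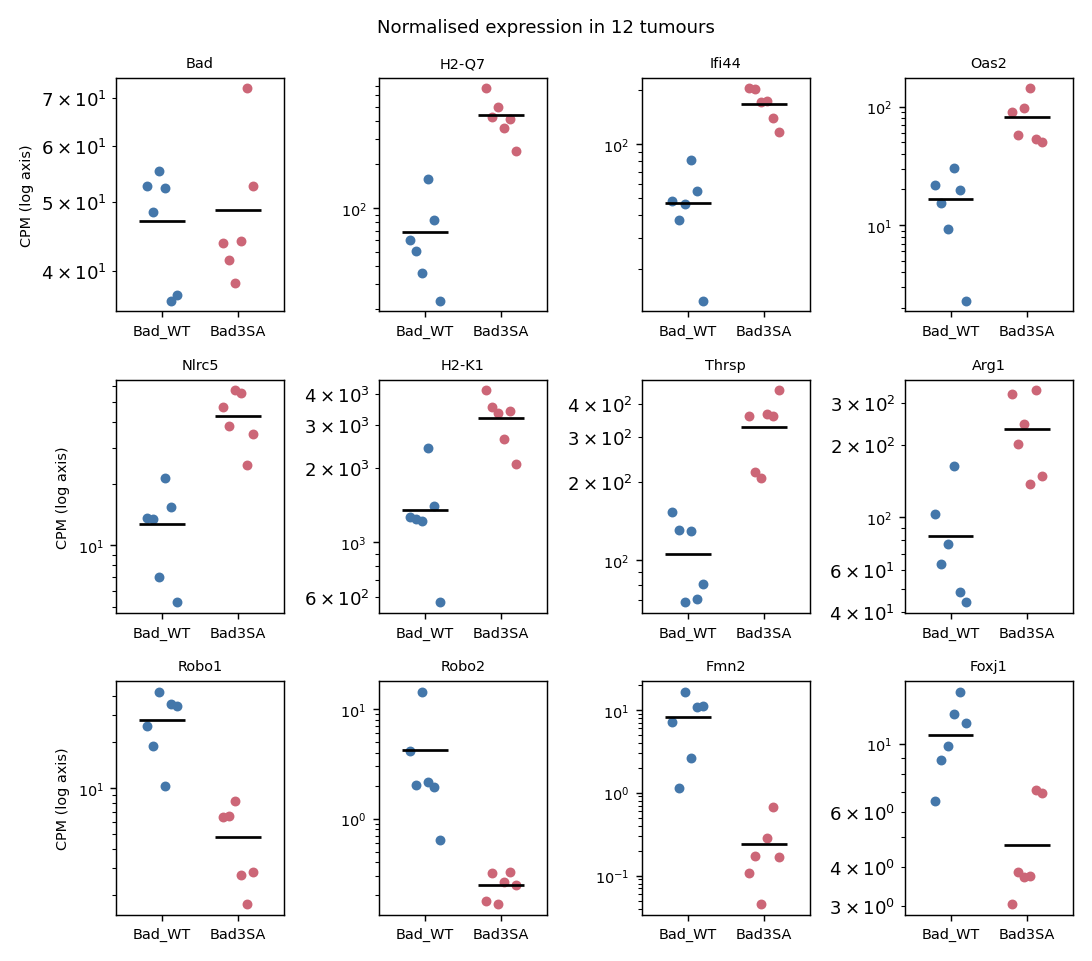
Normalised expression in CPM (log axis, one scale per panel) of 12 named genes in each of the 12 tumours; points are tumours, blue for Bad_WT and red for Bad3SA, and the horizontal line is the mean of 6. Bad overlaps between genotypes, at 47.0 and 48.8 CPM on average, while Robo1 has no overlap.

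Interferon response genes were higher in Bad3SA tumours. All but 1 of the 29 genes in the list had a positive log2 fold change, with a median of 0.82 and all 6 Bad3SA tumours above the Bad_WT median of the list mean (camera adjusted p = 1.56e-15 at a preset correlation of 0.01, over 41 lists). The adjusted p was 0.935 with an estimated correlation. Over all genes 2 members rose, and 11 did so adjusted over the list alone. The 2 were Ifi44 (46.9 ± 22.3 CPM in Bad_WT and 168 ± 34.4 CPM in Bad3SA, log2 fold change 1.84, SE 0.32, edgeR adjusted p = 0.0112) and Oas2, a sensor of double-stranded RNA (2.31, SE 0.48, edgeR adjusted p = 0.0315). Psmb8 and Stat2 stood at 1.15 and 0.80 with adjusted p of 0.0929 and 0.110 in edgeR. Both passed in the authors' deposited comparison (DESeq2 adjusted p = 0.0164 and 0.0439). Bad_WT 6 had the lowest mean of this list, 3.57 log2 CPM against 5.16 in the next Bad_WT tumour, and was also lowest for T cell, NK cell, B cell and fibroblast markers.

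Antigen presentation genes followed a similar direction in part. Of 18 genes in the list of MHC class I and II antigen presentation, 11 were positive and 7 negative, with a median of 0.17 (camera adjusted p = 8.04e-04; adjusted p = 0.935 with an estimated correlation). The median was 0.0188 without Bad3SA 2 and 0.35 without Bad_WT 4, and it was also lower by over 1.5 times without Bad3SA 5, Bad_WT 5 or Bad_WT 6, the list passing each time. With end-point age in the model it was -0.18 and the list no longer passed (adjusted p = 0.322), nor did it in tumours 4 to 6 alone, a subset chosen after seeing the data (adjusted p = 0.0898). Nlrc5, the transactivator of class I genes, rose by log2 1.76 (SE 0.32, edgeR adjusted p = 0.0143) and H2-K1 by 1.24 (SE 0.28, edgeR adjusted p = 0.0452). Tap1 and H2-D1 stood at 0.84 and 1.03 and in edgeR passed only when adjusted over the list alone, where 5 genes did. In the authors' deposited comparison both passed over all genes (DESeq2 adjusted p = 0.0180 and 0.0282). T cell markers had a median of 0.54 over 22 genes, 20 of them positive (camera adjusted p = 0.00228; adjusted p = 0.935 with an estimated correlation), and no member passed, Cd3d standing at 1.03 and Cd4 at 0.63. Without Bad_WT 6 the T cell list no longer passed (adjusted p = 0.0578), nor with end-point age in the model (adjusted p = 0.706) or in tumours 1 to 3 alone, also chosen after seeing the data (adjusted p = 0.278). In the macrophage list, which did not pass, Arg1 rose by 1.49 (SE 0.34, edgeR adjusted p = 0.0489).

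Part of the milk protein genes were higher in Bad3SA, on a wide spread. The secretory luminal list had 13 of 17 genes positive, a median of 0.54, and a list mean above the Bad_WT median in all 6 Bad3SA tumours (camera adjusted p = 0.00290; adjusted p = 0.803 with an estimated correlation). The call was lost in tumours 4 to 6 alone (adjusted p = 0.0898). None passed over all genes and 5 did adjusted over the list alone. The casein gene Csn1s1 was at 45.9 ± 28.2 CPM in Bad_WT and 829 ± 1302 CPM in Bad3SA (log2 fold change 4.17, SE 1.02, edgeR adjusted p = 0.0682), and Wap, the whey acidic protein gene, at 6.65 ± 4.71 and 59.4 ± 92.1 CPM (3.15, SE 0.77, edgeR adjusted p = 0.0679). Single tumours carried much of both means, Csn1s1 being at 3348 CPM in Bad3SA 6 and Wap at 247 CPM in Bad3SA 5. Csn1s1 in Bad3SA 2 and 3, at 36.7 and 76.8 CPM, lay within the Bad_WT range of 18.3 to 94.4 CPM. In the authors' deposited comparison Csn1s1 passed (DESeq2 adjusted p = 0.01375) and Wap had no adjusted p. Csn3 and Lalba, named after their values were seen, were on average more abundant in Bad_WT, Csn3 at 7312 ± 3655 and 5690 ± 1199 CPM (-0.36, SE 0.29) and Lalba at 417 ± 505 and 231 ± 127 CPM (-0.85, SE 0.73), and neither passed.

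All 22 cholesterol synthesis genes were negative, with a median of -0.38 (camera adjusted p = 4.85e-06; adjusted p = 0.935 with an estimated correlation). In tumours 1 to 3 alone, a subset chosen after seeing the data, the median was -0.0485 and the call was lost (adjusted p = 0.77). The list mean was 4.60 to 5.05 log2 CPM in Bad_WT 1, 2 and 3, 5.26 to 5.40 in Bad_WT 4, 5 and 6, and 4.51 to 4.88 in Bad3SA. In edgeR no member fell over all genes and 7 did adjusted over the list alone. Cyp51, Dhcr7 and Sqle stood at -0.61, -0.50 and -0.52. In the authors' deposited comparison Cyp51 and Dhcr7 passed (DESeq2 adjusted p = 0.0441 and 0.0352) and Sqle did not (0.08855). In the fatty acid synthesis list, which did not pass, Thrsp, a regulator of lipogenesis, rose from 106 ± 36.6 to 328 ± 95.8 CPM (log2 1.63, SE 0.25, edgeR adjusted p = 0.00496). Adipocyte markers had a median of 1.00 with 14 of 15 positive (camera adjusted p = 0.00290; adjusted p = 0.935 with an estimated correlation) and none passed. Fabp4 stood at 1.75 (SE 0.82), with 111 CPM in Bad3SA 5. Without Bad3SA 5 the list no longer passed (camera adjusted p = 0.0526), and with end-point age in the model its median was -0.63 and it did not pass (adjusted p = 0.821), nor did it in tumours 4 to 6 alone (adjusted p = 0.0616).

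Ribosomal protein and respiratory chain genes were slightly higher on average, with overlap between tumours of the 2 genotypes. All 30 cytosolic ribosomal protein genes were positive, with a median of 0.25 (camera adjusted p = 2.55e-05; adjusted p = 0.935 with an estimated correlation), and none passed. The list mean was above the Bad_WT median in 4 of 6 Bad3SA tumours (exact permutation p = 0.128, unadjusted). Bad3SA 2, 3 and 4, at 9.92, 9.88 and 9.97 log2 CPM, lay within the Bad_WT range of 9.72 to 10.23. These genes varied together, with an estimated correlation of 0.867. Without Bad3SA 5 the median log2 fold change was 0.166. Rplp1, Rps23 and Rpl11 have between 3 and 13 near-identical copies. Nuclear genes of oxidative phosphorylation had a median of 0.27 with 28 of 34 positive (camera adjusted p = 0.00185; adjusted p = 0.935 with an estimated correlation), among them Cox4i1 at 0.48 and Ndufa5 at 0.54. The list mean was above the Bad_WT median in 4 of 6 Bad3SA tumours (exact permutation p = 0.158, unadjusted). It was highest in Bad3SA 5, and without that tumour the median log2 fold change was 0.0902 and the camera adjusted p 0.0948. The list did not pass with limma voom (median 0.0660, adjusted p = 0.144) or with end-point age (0.0896, adjusted p = 0.141), nor in tumours 1 to 3 alone (0.0243, adjusted p = 0.596). Erythroid genes had a median of 1.20 with all 8 positive (camera adjusted p = 6.49e-04; adjusted p = 0.935 with an estimated correlation), and 5 passed adjusted over the list alone. The list mean was 0.895 to 1.13 log2 CPM in Bad_WT 1, 2 and 3 and 2.17 to 2.69 in Bad_WT 4, 5 and 6, against 3.41, 3.32, 3.42 and 2.96 in Bad3SA 1 to 4 and 2.08 and 1.69 in Bad3SA 5 and 6. In tumours 4 to 6 alone, a subset chosen after seeing the data, the median was -0.0835 (adjusted p = 0.538). Hbb-bs stood at 1.33 (SE 0.43), and Hba-a1 and Hba-a2 are 99.8% identical.

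Focal adhesion and immediate-early genes were lower in the main model, and neither list held in all others. In the cell migration and focal adhesion list 27 of 29 genes were negative, with a median of -0.25 (camera adjusted p = 2.12e-04; adjusted p = 0.935 with an estimated correlation). The call ended with limma voom (adjusted p = 0.0577) and with end-point age (adjusted p = 0.0894). No member passed, Parva standing at -0.58 (SE 0.18) and Itgav at -0.49 (SE 0.16). Of 16 immediate-early genes 13 were negative, with a median of -0.42 (camera adjusted p = 0.0332; adjusted p = 0.935 with an estimated correlation), and 2 passed adjusted over the list alone. Nr4a1 stood at -0.68 and Egr1 at -1.29, with edgeR adjusted p of 0.0659 and 0.147. Both passed in the authors' deposited comparison (DESeq2 adjusted p = 0.0110 and 0.0353). Bad_WT 5 and 6 had the highest means of this list, 6.35 and 6.28 log2 CPM, and its adjusted p was 0.217 without Bad_WT 5, 0.322 without Bad_WT 6, 0.0948 without Bad3SA 5 and 0.115 without Bad3SA 6. Heat shock genes were also highest in those tumours, at 8.13 and 8.14 log2 CPM against 6.81 to 7.28 in the other 10. The immediate-early median turned to 0.0153 with limma voom (adjusted p = 0.926) and to 0.0530 with end-point age (adjusted p = 0.816). In tumours 1 to 3 alone, a subset chosen after seeing the data, the focal adhesion median was 0.0776 (adjusted p = 0.596), and the immediate-early list passed in the opposite direction, with a median of 0.44 (adjusted p = 5.34e-06). No list held with an estimated correlation or in fry's directional test. In fry's test for change in either direction 5 of the 41 lists passed. These were the interferon, antigen presentation and secretory luminal lists, and motile cilium genes and fatty acid synthesis, which did not pass camera.

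Of the 26 named genes that passed, 17 did so with each of the 12 tumours left out in turn. Arg1 lost its call in 10 of those 12 fits, Grik3, Atp6v0e2, H2-K1 and Foxj1 in 9 each, Oas2 in 8, Dcaf12l1 in 7, and Rps3a3 and Them5 in 6 each, with edgeR adjusted p of at most 0.137. With end-point age in the model 17 of the 26 no longer passed, among them Ifi44 (edgeR adjusted p = 0.0718), Nlrc5 (0.0722), Thrsp (0.0538), Robo1 (0.178) and Robo2 (0.0931), while BC018473, St6galnac1, Ifi44l, Hmga1b, Nanos3, Dcstamp, H2-Q7, Lrmda and Snhg18 did.

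**Figure D2:**
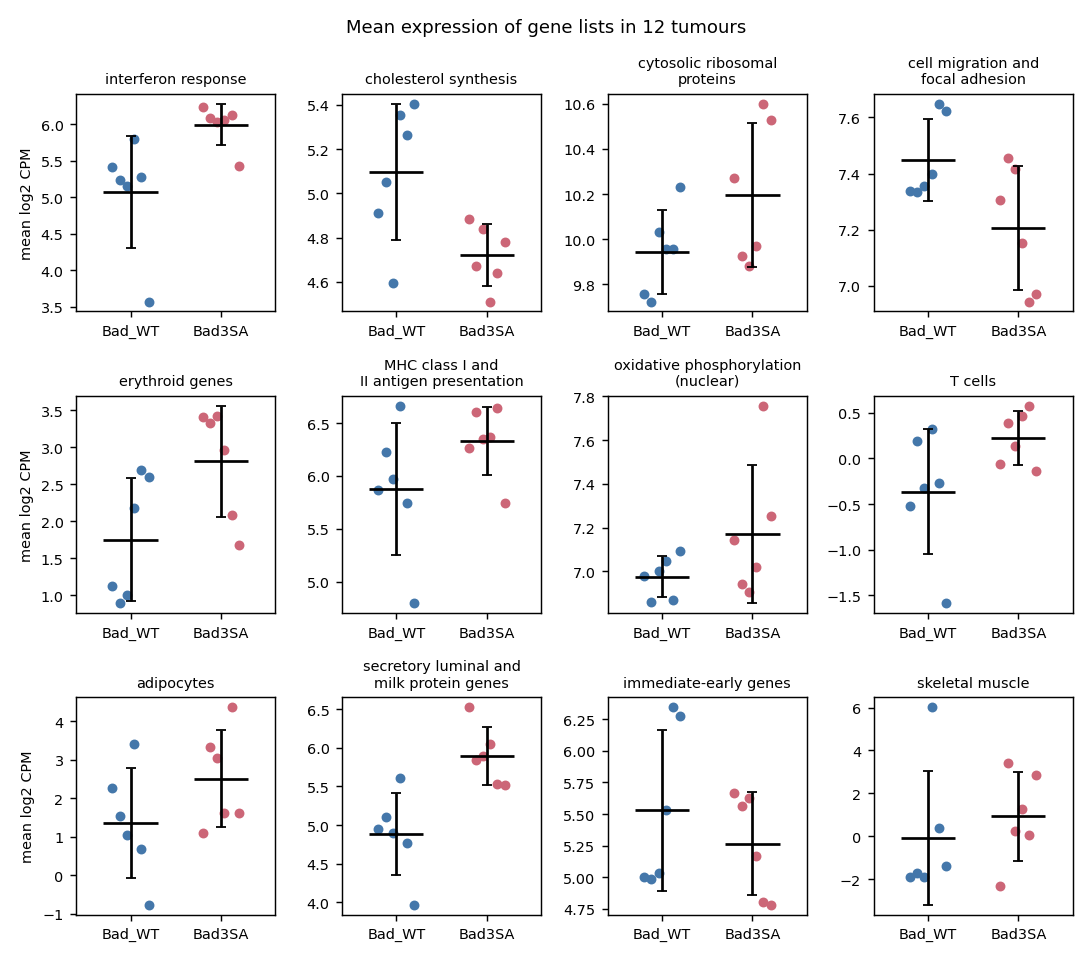
Mean log2 CPM of the 11 gene lists that passed the camera test and of skeletal muscle markers, in each of the 12 tumours; points are tumours, the horizontal line is the mean of 6 and the bars are 1 SD. Bad_WT 6 is the lowest tumour for interferon response at 3.57, and Bad_WT 4 the highest for skeletal muscle at 6.01.

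The other 30 lists did not pass. Camera adjusted p was 0.0588 for heat shock genes and for NK cells, 0.0871 for macrophages and for fatty acid oxidation, 0.138 for Schwann cell genes and for hypoxia and glycolysis, 0.148 for BAD kinases, phosphatases and 14-3-3 proteins, and 0.169 for basal and myoepithelial genes. It was 0.191 for mast cells, 0.192 for fibroblasts, 0.234 for B cells and for proliferation, 0.248 for p53 targets, and 0.442 for neutrophils, plasma cells and hormone-sensing luminal genes. Fibrillar collagens and the BCL2 family stood at 0.476, DNA replication and mitochondrially encoded genes at 0.556, the unfolded protein response at 0.625 and apoptosis execution at 0.732. Motile cilium genes, fatty acid synthesis, the TCA cycle, endothelial cells and dendritic cells stood at 0.933 and the epithelial-mesenchymal transition at 0.970. Among motile cilium genes Foxj1, the regulator of ciliogenesis, fell by 1.18 on the log2 scale (SE 0.26, edgeR adjusted p = 0.0473). Squamous keratinocyte genes had a negative median of -0.81 and a camera direction of higher (adjusted p = 0.111), and skeletal muscle genes a median of -2.02 and again a direction of higher (adjusted p = 0.668). Both lists were highest in Bad_WT 4, at 5.09 and 6.01 log2 CPM.

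Bad3SA mice were older at their end point on average. The series text describes the mice as matched for age, while the ages in the labels differ. The mean was 24.0 ± 1.93 weeks in Bad_WT and 27.5 ± 2.85 weeks in Bad3SA (SD, n = 6 each), a difference of 3.40 weeks (exact two-sided permutation p = 0.0433). The difference in medians was 4.00 weeks (exact permutation p = 0.0628). Leaving out a single mouse took the exact permutation p of the mean above 0.05 for 9 of the 12 mice, to between 0.0519 and 0.0866. With age in the edgeR model 73 genes differed between genotypes, 50 higher and 23 lower, and 69 of them also did without age. No gene passed for the slope with age. Of the 18019 genes, 1520 had an unadjusted edgeR p under 0.05 for that slope, a share above 0.05. Age and genotype correlated at 0.608, so their effects were only partly separable and an effect of age was not excluded. All 249 genes kept their sign, and their median size moved from log2 1.65 to 1.57 while the median SE went from 0.277 to 0.353.

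The authors' deposited table holds 952 genes at an adjusted p under 0.05, 453 with a negative and 499 with a positive log2 fold change. Its sign is that of Bad_WT relative to Bad3SA, since its fold changes and those fitted here correlate at a Spearman rho of -0.997 across 18019 genes, which are not independent replicates. All 249 genes called here were also called in the authors' deposited table with the matching direction. DESeq2 run here called 998 genes, 945 of them in common with the authors' deposited table.

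No excess of differing genes was detected around Bad. Within 5 Mb of Bad 2 of 271 genes tested differed, Chrm1 and Gm6252, which were named after their values were seen, against 247 of 17747 elsewhere (odds ratio 0.527, 95% interval 0.0631 to 1.94, Fisher's exact two-sided p = 0.594). Within 20 Mb there were 6 of 331, an odds ratio of 1.33 (0.478 to 2.96, Fisher's exact p = 0.469).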

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

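The test with leukocyte markers was set before its result was seen, as were those of other splits, of age for the called genes and of genes near Bad. The remaining tests of this part were chosen after the pattern was seen. Among 230 sets of 6 values, 16 had a tumour whose gap to the next, over the range, passed Dixon's critical value for 6 samples. Chance gives about 1 in 20 sets.

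Bad_WT 6 was lowest of its genotype for St6galnac1 (gap over range 0.738), Stat2 (0.723), Tap1 (0.652), the interferon list (0.712) and the NK cell list (0.716). The St6galnac1 gap lies near the count floor, at 0 CPM in Bad_WT 6 and 0.126 to 0.255 CPM in the other Bad_WT tumours. Bad_WT 4 was highest for skeletal muscle genes (0.708) and squamous keratinocyte genes (0.722). Bad3SA 5 was highest for Cox4i1 (0.648), Ndufs3 (0.679), Psmb8 (0.787) and Wap (0.713). Bad3SA 6 was lowest for Bcl2l11 (0.738), Cd4 (0.636), Nr4a1 (0.632), the interferon list (0.751) and the hormone-sensing luminal list (0.686).

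The interferon genes were weighed against 3 explanations. The tables argue against Bad_WT 6 as the whole cause, since without it the list median was 0.642 against 0.82 with it. More leukocytes in the Bad3SA tumours and the older age of those mice stay open. The genotype difference of the list mean was 0.92 (SE 0.335), and it was 0.50 (SE 0.189) with leukocyte markers and 0.71 (SE 0.43) with age in a linear model, neither clear of 0.46 by more than its SE. A direct effect of genotype was not separated from these. Ifi44, which passed over all genes, lies next to Ifi44l on chromosome 3, and a sequence difference at that place was not tested.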

How the results depend on the processing

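Results with 3 tumours left out, with titles 1 to 3 or 4 to 6 alone or as a term, and the permutation of list means were chosen after seeing the data. The first set of 3 tumours (Bad_WT 4, Bad_WT 6, Bad3SA 2) was picked by eye and gave 234 genes; a later rule on gaps between list means replaced Bad3SA 2 by Bad3SA 6 and gave 345 genes, 173 higher and 172 lower, with Bad at -0.00746. The split by title number was also picked by eye and no label makes it a batch. Titles 1 to 3 gave 1201 genes (591 higher, 610 lower) and titles 4 to 6 gave 73 (39 and 34). All called genes tested in them, 249 and 247, kept their sign. That is no separate check, since in 211 of the called genes the 2 genotypes did not overlap, so a subset could hardly change the sign. The causes of the changes below were not tested.

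The DESeq2 Wald test called 998 genes (479 higher, 519 lower) with 945 shared with the authors, voom 579 (231 and 348), a minimum of 1 CPM 163 (86 lower), and an adjusted p under 0.1 455. With age there were 73 (50 and 23). No pairing by title number was detected in expression. Residual correlations of pairs ran from -0.271 to 0.283 and 1 of 6 was over 0.1. Of the 6 Bad_WT tumours 1 correlated best with its own number. A pairing in breeding or handling was not tested. The replicate block gave 105 genes (63 and 42). Leaving out a tumour gave 147 to 315 genes (73 to 153 higher, 61 to 162 lower), and 117 genes remained in each of the 12 fits. The lowest count, 147, came without Bad_WT 5, and counts also moved by over 1.5 times without Bad_WT 1 (158), Bad_WT 3 (161), Bad3SA 3 (151) and Bad3SA 4 (148). Bad had no call in any setting. It was -0.17 with voom, -0.19 with age, -0.36 in titles 1 to 3, and -0.10 to 0.12 with a tumour left out.

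No filter gave 17 lists, leaving out a tumour 9 to 22 (22 without Bad_WT 4), and estimated correlation, fry and permutation of list means 0, the last with 5 lists at an unadjusted p under 0.05. Immediate-early genes were at 0.0153 with voom, -0.39 at 1 CPM, 0.0530 with age, -0.29 with the block, 0.44 in titles 1 to 3, where the list was called higher (adjusted p = 5.34e-06), -0.32 with the title term, -0.31 and -0.21 without 3 tumours, and -0.53 to -0.21 with a tumour left out. Focal adhesion genes were at -0.0992 with voom, -0.0852 with age and 0.0776 in titles 1 to 3; oxidative phosphorylation at 0.0660, 0.0896 and 0.0243, and 0.0902 to 0.34 with a tumour left out. The MHC, T cell, adipocyte, focal adhesion and oxidative phosphorylation calls ended with age, focal adhesion and oxidative phosphorylation also with voom, and immediate-early genes with voom, 1 CPM, age and the block. With age MHC genes were at -0.18 with a camera direction still higher, T cells at 0.0577 and adipocytes at -0.63. Titles 1 to 3 gave cholesterol synthesis -0.0485 and T cells 0.16, and titles 4 to 6 gave MHC genes 0.29, adipocytes 1.16, milk genes 0.50 and erythroid genes -0.0835; each of these calls was lost, as were focal adhesion and oxidative phosphorylation in titles 1 to 3. With a tumour left out T cells ran from 0.35 to 0.68 and adipocytes from 0.65 to 1.83, MHC genes from 0.0188 to 0.35 and ribosomal genes from 0.166 to 0.32. Interferon and ribosomal genes passed in every fit at the preset correlation of 0.01. Their estimated correlations in the main fit were far higher, at 0.674 and 0.867, and neither list passed with those.

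With age Fabp4 was at -0.72 and Retn at -1.32. In titles 1 to 3 Pmaip1 was at 0.38, Bcl2l13 at 0.00221 and Ier3 at 0.25, and in titles 4 to 6 Bcl11b at -0.14. Median age differed by 4.00 weeks (p = 0.0628 by exact permutation), and leaving out a mouse gave 2.67 to 4.32 weeks. The odds ratio near Bad was 1.33 within 20 Mb.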

Other observations

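The tests of linked stretches of chromosome and of pseudogene parents were chosen after the called genes had been seen; those of other splits, age and genes near Bad were set before.

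Chance alone was unlikely to give the count of differing genes, but it was not excluded. Of 100 splits of the 12 tumours drawn from 462, only the real split reached 249 genes, and the highest other gave 134. That other split grouped 5 Bad_WT tumours with Bad3SA 6, so it stayed close to the real split. The splits that were not drawn were not fitted. The ratio of the median fold change of the called genes with age in the model to that without was 0.957. These genes were chosen for their genotype difference without age, which favours a ratio near its full size. The ratio therefore does not settle the part of age. The count of calls went to 73 as the standard errors grew, from 112 to 50 higher and from 137 to 23 lower. Near Bad the upper bound of the odds ratio was 1.94, which argues against an excess of differing genes over 2-fold within 5 Mb as flanking variants would give. Within 20 Mb the odds ratio was 1.33 with an upper bound of 2.96, so a wider stretch stays open, and counts of genes do not measure variants.

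Several genes were present in one genotype and almost absent in the other, so a difference in inherited sequence between the mice might contribute. Called genes often had another called gene within 1 Mb, 42.3% of them against 30.7% on average in 10000 random draws of tested genes, of which 18 were as high. The same number of smallest-p genes reached as high a percent in 17 of the 99 other splits, up to 50.4%, and splits that mix the genotypes can carry such stretches too. The bound set for this test therefore excludes nothing, and linked sequence differences and coordinated expression of neighbours cannot be told apart here. BC018473 and St6galnac1 are neighbours on chromosome 11, and Foxj1, which fell, lies within 1 Mb of both, at 116330704 to 116335399. Ifi44 (151730922 to 151749960) and Ifi44l (151758737 to 151762892) are neighbours on chromosome 3. Whether single on and off genes such as BC018473 carry sequence differences was not tested, and the labels give C57BL/6J for all mice.

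Pseudogenes were called higher in 32 of 33 cases against 60 of 184 protein-coding genes (Fisher's exact two-sided p = 6.41e-13). That p treats genes as independent, while the 30 of these 32 with a tested parent had only 26 distinct parents. Reads of parent genes may be counted on the copies. The 26 distinct parents of those pseudogenes had a median log2 fold change of -0.0933, against 0.0957 for 479 parents of other pseudogenes (permutation p = 0.00362). Of the 26, 16 had a log2 fold change below 0, and 6 passed the threshold as lower while 2 passed as higher. Capza1-ps1 was higher by log2 5.14 and Capza1, 99.5% identical, had a log2 fold change of -1.55. The shift in the parents is small, and a change in the copies themselves stays open.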
